A study of Mus musculus with 7 samples.

How the data were processed

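Capture Hi-C was used to count contacts between pairs of loci within a 10 Mb region around Epha4 on mouse chromosome 1. Chromatin was cut with DpnII and religated, and fragments from the region were enriched with probes before sequencing, per the labels' protocols. There were 7 libraries with 1 library per condition: WT limb buds, Inv1, Inv2, Inv3, Inv4 and Inv1DelCTCF limb buds at stage E11.5, and Inv1 embryonic stem cells (ESCs). Each limb bud library pooled 10 embryos, per the series design text. Groups were taken from the sample titles, which for the limb bud libraries also read Distal. The cell type and tissue fields carry the same entry for every library, so the ESC library was identified by its title and the design text alone.

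The genome build was mm9 and the tools were Bowtie2 2.2.6 and Juicer, per the submitters' processing notes; which step each tool served was not given in the sources used here. The deposited maps list 1 signal value for each pair of 10 kb bins between 71 and 81 Mb, balanced by the authors with the Knight-Ruiz method per the file names, so that every bin has the same sum. Maps were deposited for all 7 libraries. For WT and the 4 inversions the authors also deposited a table with 1 scaled contact signal per gene, between its transcription start site and an enhancer region. The scaling was not given in the sources used here. The tables do not state where the genes or the enhancer region lie, and each table was scaled by the authors on its own. The planned percentile of each gene among distance-matched bin pairs was therefore not computed. All 103 gene symbols were found in the RefSeq table for GRCm38.p6, 98 as current symbols and 5 as synonyms. No coordinate of that table was used. Of the genes, 30 shared all their values with another gene, since neighbouring start sites can fall in one interval.

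Balanced values without negatives were whole read pairs multiplied by 1 factor per bin. Read pairs were recovered by fitting these factors, and in WT, Inv1, Inv1DelCTCF and Inv1 ESC 100.0% of values under about 20 read pairs lay within 0.1 of a whole number. Recovered totals were 5190282 for WT, 3903623 for Inv1, 3997486 for Inv1DelCTCF and 4319735 for Inv1 ESC. The Inv2, Inv3 and Inv4 maps contained negative values at 29.7%, 31.3% and 28.8% of listed bin pairs. Of the 107735, 110593 and 101804 negative bin pairs with WT signal at the same coordinates, 73.3%, 72.7% and 73.2% lay within 1% of 1 constant multiple of the WT map. These 3 maps therefore held a library minus the WT map, weighted by 0.423, 0.369 and 0.334. The subtracted signal amounted to 49.3%, 49.4% and 49.1% of the original bin sum. The file names mark these 3 maps as hom, but the labels describe neither this step nor whether the embryos carried a WT chromosome beside the inverted one. The Inv2 to Inv4 values are those of the inverted chromosome only if the subtracted share was the WT part of the library. Adding it back outside the inversions gave 3592214, 3135499 and 2823908 read pairs for Inv2, Inv3 and Inv4, against 4297032 for WT in the same area. Depth inside the inversions was not recovered for these 3 libraries, and their counting errors are approximate.

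The fitted bin factors also gave the coordinate frame. Within each inverted segment the factors matched those of WT read backwards and not forwards, so mutant maps were written in the coordinates of the rearranged chromosome. For Inv2 to Inv4 the factors were read from the negative values, so they are those of the subtracted WT map. The mutant maps were turned back to WT order only where a sentence compares the same sequence. The best match for Inv1DelCTCF was a few kb shorter than for Inv1 within the segment, which is poorly determined, and the labels do not describe the deletion.

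Contact at each distance was divided by its mean in the same map (observed over expected). Bins with under 25% of the median number of listed pairs were left out. Contact shares were the summed balanced signal of a locus with a region, as a percent of all its contacts. Insulation was the log2 of mean contact in a 200 kb square across each bin over its mean. A boundary was a local minimum with a depth of at least 0.2 within 300 kb. The stripe score was the log2 ratio of observed over expected contact of a 3-bin anchor over 100 to 1500 kb on one side, against bins 3 to 8 on either side of it. The highest score within 20 kb of the mapped anchor was taken. The footprint score compared 10 by 10 bin squares around pairs of bins at least 200 kb apart. Map-wide change and map similarity used bin pairs 50 to 2000 kb apart, with a pseudocount of 0.5 on observed over expected. Log2 ratios of the gene tables used a pseudocount of 0.5, with negative values set to 0 first, which understates changes at low values.

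With 1 library per condition, no test between conditions was possible and no p-value is given. Counting intervals (95%) were computed from the recovered read pairs, and those of stripes from 100 Poisson redraws. They cover counting error only and say nothing of the spread between embryos. The spread outside the inversions was used as a description of these libraries: 35 genes at both ends of the tables for gene contacts, and 788 bins for stripes. The 788 bins were scored without the search within 20 kb that the anchor had, so their SD leaves out that search. These 35 genes, the gene blocks and the map regions between breakpoints were defined after the tables and breakpoints had been seen.

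The text names Epha4, Pax3, Wnt6, Wnt10a, Ihh, Cdk5r2, Des, Slc4a3, Sgpp2, Farsb and Mogat1, plus in each inversion the 8 genes with the largest absolute log2 ratio to WT. The 3 gene lists were secreted limb signals (3 genes), genes of the Epha4 and Pax3 domains (6) and gene-dense neighbours (45). These rules and the alternatives (scaling, pseudocount, bin size, window, threshold and distance range) were set before the data were examined.

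The procedures were tested on simulated data. Of 339615 simulated bin pairs with reads, 99.3% of counts were recovered. For 10 simulated stripes with a log2 height of 0.58 the mean score was 0.59 ± 0.026 (SD). These stripes lay on the mean contact of each distance, without domain borders, and were scored at their known bin. The test therefore does not cover an anchor beside a border or the search for the highest score. In the simulated comparison of Inv1 with WT over 103 genes, all genes raised 8-fold were called (100.0%) and 72.4% of those raised 3-fold, with 1.51% and 1.31% of unchanged genes called. Genes lowest in WT were not among those raised, the noise was the far-gene SD of Inv1 (0.321), and only upward calls were counted. These rates do not cover Inv2 to Inv4, where that SD was 0.406, 0.608 and 0.601. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.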

Results

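Serial CRISPR/Cas9 inversions near Epha4 were compared with WT chromosomes by capture Hi-C in mouse limb buds (titled Distal) at stage E11.5. Epha4 encodes an ephrin receptor tyrosine kinase of the limb bud. The libraries were WT, 4 inversions (Inv1 to Inv4), Inv1 with a deletion that its label names after CTCF (Inv1DelCTCF) and Inv1 ESCs, which are pluripotent cells in culture. CTCF is a DNA-binding protein found at domain borders and stripe anchors. Each condition was 1 library, so all differences below are between libraries and have no replicate check. The WT map held 5190282 read pairs and the Inv1, Inv1DelCTCF and Inv1 ESC maps 3903623 to 4319735. The Inv2 to Inv4 maps were deposited after a share of WT signal had been subtracted and contained negative values, so their low values were noisier. Whether these embryos also carried a WT chromosome was not stated in the labels, and values of Inv2 to Inv4 are those left after the subtraction.

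The gene tables addressed which promoters met the enhancer region on each chromosome. In WT limb buds the highest contact was that of Epha4, at 7.68 scaled units. Epha4 was at 0.487 in Inv1, 1.54 in Inv2, 1.995 in Inv3 and 1.25 in Inv4, which is 6.34%, 20.02%, 26.0% and 16.3% of WT on the deposited scales. The tables were scaled one by one, and the order of Inv2 to Inv4 depended on this: the log2 ratio of Epha4 to WT was -3.05 in Inv1, -2.01 in Inv2, -1.71 in Inv3 and -2.22 in Inv4, and -3.67, -2.01, -2.52 and -3.31 when ratios were centred on the median gene. Centring may also remove signal where many genes gained contact. In its place, a different set of genes of the gene-dense neighbourhood peaked in each inversion: Ptprn at 22.99 in Inv1, Nhej1 at 20.04 in Inv2, Fev at 36.4 in Inv3 and Prkag3 at 33.9 in Inv4. Nhej1 encodes a factor of DNA end joining, Fev an ETS transcription factor of serotonergic neurons, and Prkag3 a subunit of the AMP-activated kinase. In WT these 4 genes were at 1.35, 0.709, 1.31 and 1.01. Over 35 genes at the far ends of the tables, the SD of the difference to WT was 0.321 in Inv1, 0.406 in Inv2, 0.608 in Inv3 and 0.601 in Inv4.

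**Figure D1:**
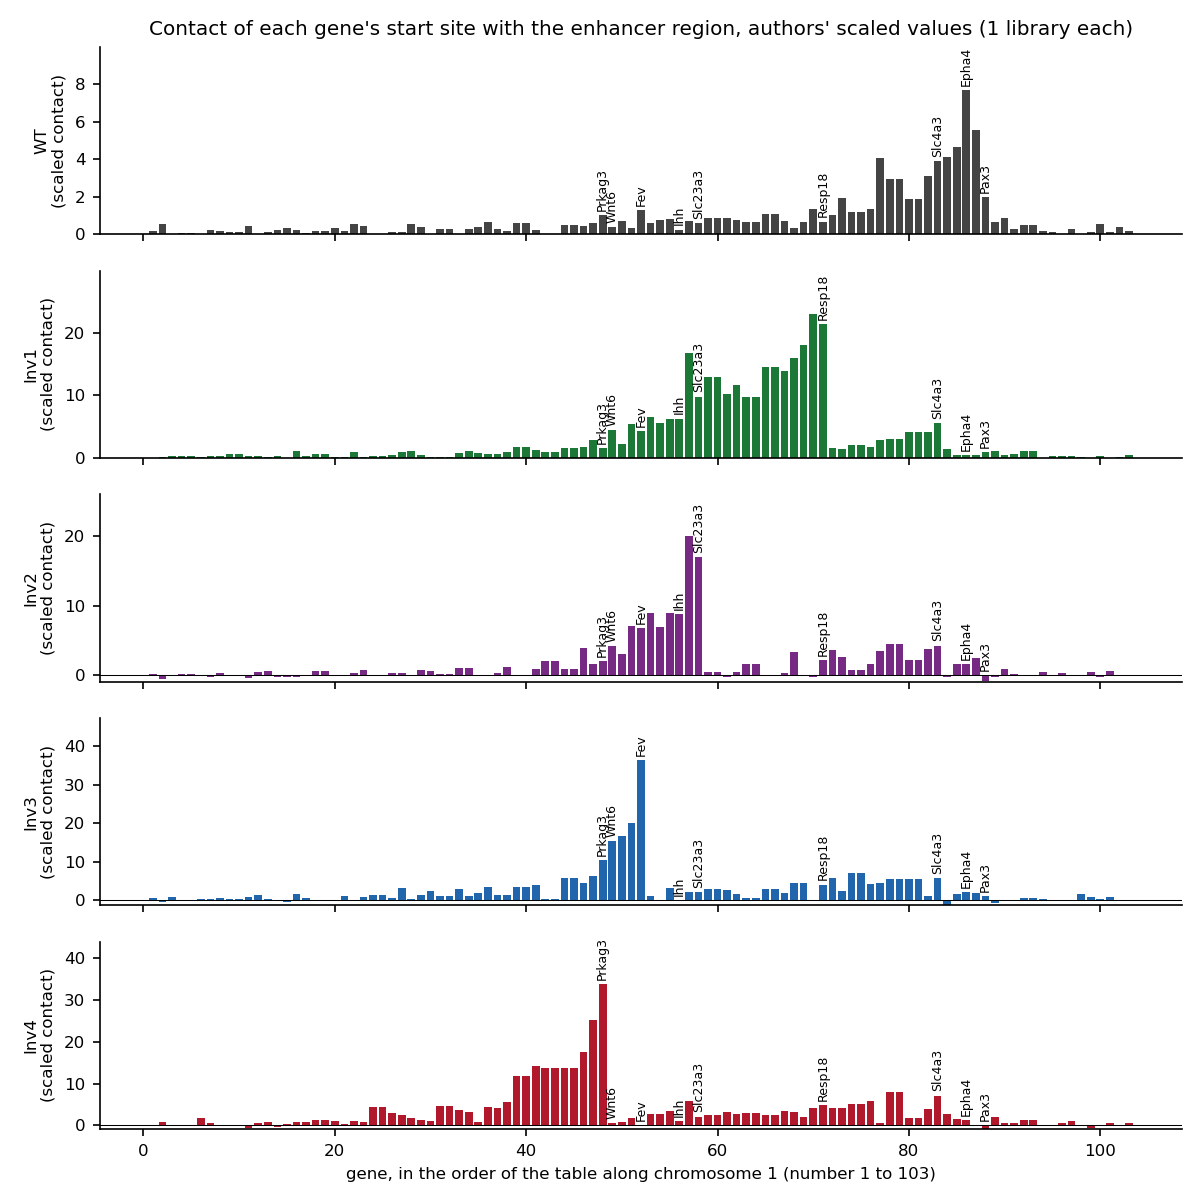
Scaled contact of each gene's start site with the enhancer region (y axis, authors' units, scales differ between panels) for 103 genes in table order (x axis), 1 library per panel and 1 bar per gene. The peak lies at Epha4 in WT (7.68) and at Ptprn, Nhej1, Fev and Prkag3 in Inv1 to Inv4, each followed by an abrupt fall.

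The secreted limb signals Wnt6, Wnt10a and Ihh met the enhancer region to a different extent in each inversion. Wnt6 and Wnt10a encode Wnt ligands and Ihh a hedgehog ligand that acts on growing cartilage. All 3 were over 2-fold above WT in Inv1 and Inv2, except that the log2 ratio of Wnt10a in Inv1 fell from 1.17 to 0.55 after centring, and that with a pseudocount 10 times larger 1 of the 3 passed in either inversion. Wnt6 was at 0.401 in WT, 4.41 in Inv1 and 4.22 in Inv2, and Ihh at 0.260, 6.31 and 8.85. In Inv3, Wnt6 reached 15.4 and Wnt10a 16.6, against 0.697 for Wnt10a in WT, while Ihh was at -0.053, with a log2 ratio of -0.60, or -1.41 after centring. In Inv4, Wnt6 was at 0.545 and Wnt10a at 0.766, within 2-fold of WT, although centring put Wnt10a at -1.004 and Wnt6 at -0.87 on the log2 scale. Ihh was at 1.03 in Inv4, which is 0.77 above WT and of the order of the far-gene SD. Its log2 ratio of 1.01 there turned to -0.07 after centring.

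The genes with the largest ratios to WT differed between inversions. In Inv1 the 8 genes were A630095N17Rik, Resp18, Dnajb2, Nhej1, Ptprn, Tuba4a, Cnppd1 and Fam134a, with log2 ratios of 3.30 to 4.31. Dnajb2 encodes a co-chaperone and Tuba4a an alpha-tubulin. In Inv2 they were Nhej1 (4.09), Slc23a3 (4.01), Ihh (3.62), Cdk5r2, Cryba2, Ccdc108 and Mir375, with Gm17751 on the low side (-3.22, from a negative value set to 0). In Inv3 they were Cdk5r2 (4.57), Fev, Wnt6, Wnt10a, Prkag3, Tmbim1 and Rnf25, again with Gm17751 at -3.22. Stk36 had the same ratio as Rnf25 there (2.65) and tied with it for the last place. Cdk5r2, an activator of the kinase Cdk5, was at 0.365 in WT, 5.44 in Inv1, 7.09 in Inv2, 20.05 in Inv3 and 1.81 in Inv4. In Inv4 the 8 genes were Zfp142, Bcs1l, Prkag3, Cyp27a1, Plcd4, Ttll4, Rnf25 and Stk36, with log2 ratios of 3.85 to 4.83. Cyp27a1, a sterol hydroxylase, was at 0.633 in WT and 25.2 in Inv4. Zfp142 and Bcs1l were listed at 0 in WT. Sizes and membership of these lists depended on the settings. The 8 ratios of Inv1 ran from 1.61 to 2.22 with the larger pseudocount and from 3.83 to 5.38 with one 10 times smaller, and Resp18 in place of A630095N17Rik was the highest with the larger. Of the 8 genes, the smaller pseudocount kept 5, 4, 4 and 3 among the 8 largest in Inv1 to Inv4, the larger one 6, 7, 6 and 8, and centring 5, 8, 5 and 5.

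Of the 6 genes of the Epha4 and Pax3 domains, 1, 3, 3 and 2 were over 2-fold below WT in Inv1 to Inv4, and 3, 3, 5 and 3 after centring. With the larger pseudocount 1, 0, 0 and 1 remained below, and with the smaller one 2, 3, 4 and 2. Sgpp2 in Inv4 was the 1 gene over 2-fold above WT, at a log2 ratio of 1.14, or 0.057 after centring. Epha4 was below WT in all 4 inversions. Pax3, a transcription factor of muscle and neural crest progenitors, was at 1.98 in WT, 0.963 in Inv1, -0.870 in Inv2, 0.984 in Inv3 and -0.808 in Inv4. Slc4a3, an anion exchanger gene that precedes the Epha4 block in the table, was at 3.91 in WT and 4.26 to 7.13 in the inversions. It was put on this list in advance, and its gene order places it beside the gene-dense neighbours, so it may not belong to the Epha4 domain. Farsb and Mogat1 were at 0.853 and 0.304 in WT and between -0.112 and 0.950 in the inversions. Sgpp2, a sphingosine phosphate phosphatase gene, was at 0.667 in WT and ranged from -0.871 in Inv3 to 2.07 in Inv4. Des, which encodes the muscle intermediate filament desmin, was at 1.93 in WT and 1.40 to 4.16 in the inversions, with its log2 ratio turning after centring from 0.94 to -0.15 in Inv4 and from 0.21 to -0.59 in Inv3. That of Slc4a3 turned from 0.79 to -0.29 in Inv4, 0.51 to -0.29 in Inv3 and 0.46 to -0.16 in Inv1.

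Of the 45 gene-dense neighbours, 28 were over 2-fold above WT in Inv1, 12 in Inv2, 32 in Inv3 and 34 in Inv4, and 0, 8, 2 and 2 were over 2-fold below. After centring 16, 12, 15 and 16 were above and 1, 8, 4 and 5 below. With the larger pseudocount 15, 4, 3 and 11 were above and none below, and with the smaller one 31, 17, 36 and 38 were above and 0, 11, 2 and 2 below. Over all 103 genes, the counts above and below WT were 37 and 4 in Inv1, 20 and 17 in Inv2, 47 and 11 in Inv3, and 54 and 7 in Inv4. These counts depended on scaling and pseudocount: centred on the median gene they were 21 and 13 in Inv1, 20 and 17 in Inv2, 24 and 29 in Inv3, and 24 and 25 in Inv4. The median log2 ratio of all genes was 0.62, 0.0044, 0.81 and 1.08, and of the 35 far genes 1, 2, 8 and 7 also exceeded 2-fold. The 45 gene-dense neighbours are a large part of the 103 genes, so the median gene may itself be raised by an inversion. Centring may then remove signal along with scale, which were not told apart.

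The largest fall between neighbouring genes placed each breakpoint in gene order. Contact fell from 21.4 at Resp18 to 1.69 at Dnpep in Inv1, from 17.0 at Slc23a3 to 0.438 at Cnppd1 in Inv2, from 36.4 at Fev to 1.03 at Cryba2 in Inv3, and from 33.9 at Prkag3 to 0.545 at Wnt6 in Inv4. The 13 genes from Cnppd1 to Resp18 had a median of 0.776 in WT, 13.9 in Inv1 and 0.386 in Inv2. The 4 genes from Wnt6 to Fev had a median of 0.549 in WT, 18.3 in Inv3 and 0.655 in Inv4. These neighbours of breakpoints were singled out after the values had been seen.

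The maps were examined for the rearrangement that each label names. The best match of bin factors to WT read backwards placed the segments on chromosome 1 at 75.29 to 75.89 Mb in Inv1, 75.13 to 75.90 Mb in Inv2, 74.95 to 75.89 Mb in Inv3 and 74.81 to 75.89 Mb in Inv4. The outermost bins that differed from WT lay up to 20 kb further out, so that each breakpoint is known to within 1 or 2 bins of 10 kb. These outer limits, at 75.28, 75.13, 74.93 and 74.79 Mb on the left and taken as 75.90 Mb on the right, bound the regions below. Within the matched segment, the bin factors of Inv1 correlated with WT at 0.620 (across 60 bins, which are not replicates) when read backwards and at -0.146 when read forwards. The backward correlation was 0.762 in Inv1DelCTCF and 0.579 in Inv1 ESC. Segments were chosen for their backward match, so these values lean high. In Inv2, Inv3 and Inv4 the backward correlation was 0.630, 0.579 and 0.445. Their factors came from negative values and are those of the subtracted WT map, so they show the frame of the subtraction. The segments of Inv2 to Inv4 given above are those of that frame. Contact across the new left join was 17.5 to 43.6 times that of the same sequences in WT, and across the new right join 5.42 to 13.8 times. Contact across the former right join was 8.34% ± 0.470 of WT in Inv1, 14.1% ± 2.75 in Inv2, -7.22% ± 2.62 in Inv3 and 9.10% ± 3.08 in Inv4 (counting standard errors). It was 9.34% ± 0.512 in Inv1DelCTCF and 12.4% ± 0.556 in Inv1 ESC. Across the former left join it was 16.7% ± 0.652 in Inv1, 7.27% ± 3.37 in Inv2, 10.3% ± 3.03 in Inv3, 3.49% ± 3.34 in Inv4, 22.0% ± 0.770 in Inv1DelCTCF and 32.2% ± 0.841 in Inv1 ESC. Mean contact at the new distance would give 15.0% to 28.9% of WT in the limb bud mutants and 30.97% in Inv1 ESC. In ESCs contact across the former left join was thus not below that of its new distance. WT here is the limb bud map, so the percentages of Inv1 ESC also hold the difference in tissue. In file coordinates the footprint score at the breakpoints was 0.034 in Inv1, -0.0076 in Inv3 and 0.018 in Inv1DelCTCF. It was 0.29 in Inv2, 0.39 in Inv4 and 0.26 in Inv1 ESC, at the 99.5th to 99.9th percentile of all bin pairs scored. With squares of 5 bins in place of 10 the score was 0.18 in Inv2, 0.016 in Inv4 and 0.33 in Inv1 ESC, so the Inv4 score held for the larger squares alone. The maps are in the coordinates of the rearranged chromosome, so a low score does not speak against an inversion. Inv1 and Inv1 ESC carry the same inversion yet scored 0.034 and 0.26, so this score does not tell whether an inversion is present. Bin factors show the coordinate frame only, so the presence of an inversion rests on the joins.

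The part of the Epha4 domain that moved lay between the WT border and the shared breakpoint, at 75.62 to 75.90 Mb. In WT, 33.5% of its contacts were with the rest of that domain (75.90 to 77.51 Mb), with a counting standard error of 0.106. This share was 5.66% in Inv1, 7.97% in Inv2, 7.43% in Inv3 and 5.89% in Inv4. With the stretch from 74.79 to 74.93 Mb, bounded by the outer limits of the Inv4 and Inv3 breakpoints and hence by the falls at Wnt6 and Fev, the share was 0.418% in WT, 2.32% in Inv1, 2.71% in Inv2, 9.30% in Inv3 and 0.484% in Inv4. With the stretch from 74.93 to 75.13 Mb, which the same reading assigns to Cryba2, Ihh, Nhej1 and Slc23a3, it was 0.678% in WT, 7.40% in Inv1, 11.9% in Inv2, 0.900% in Inv3 and 1.34% in Inv4. With the 1000 kb beyond the Inv4 breakpoint it was 1.53% in WT and 21.5% in Inv4. All these differences to WT exceeded their 95% counting intervals except that of Inv4 with the Wnt6 to Fev stretch (0.402% to 0.567% in Inv4).

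**Figure D2:**
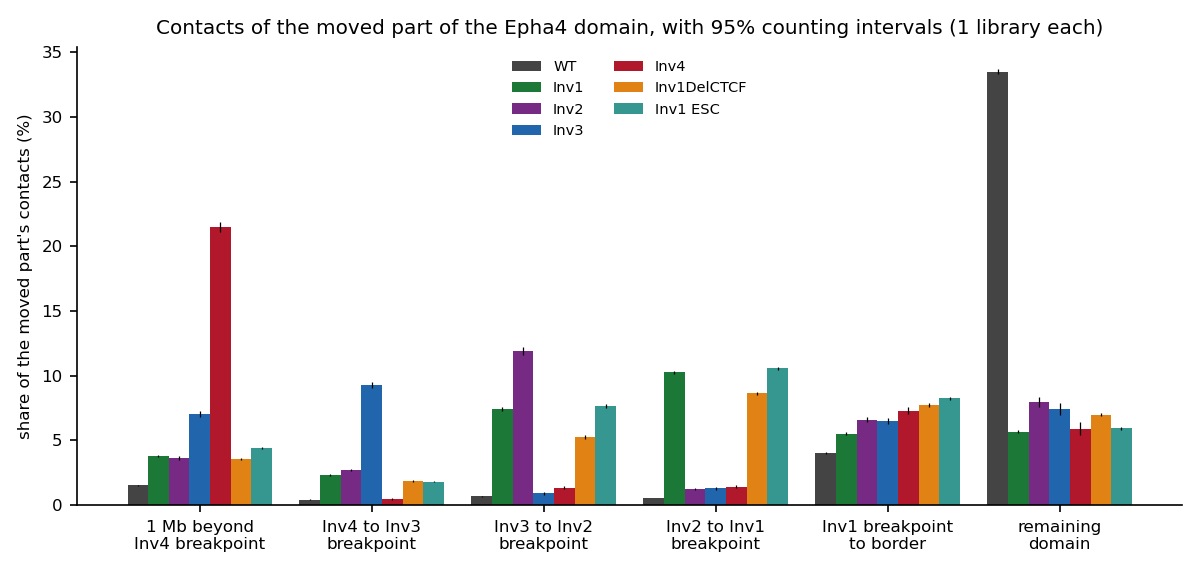
Share of all contacts of the moved part of the Epha4 domain (y axis, percent) with 6 regions in WT order (x axis), 1 bar per library with its 95% counting interval. The remaining domain held 33.5% in WT and 5.66% to 7.97% in the mutants, and the region next to each left breakpoint held the highest share of these 6 in Inv1 to Inv4.

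Domain borders outside the inversions were largely kept. Of 16 WT boundaries outside 74.79 to 75.90 Mb, 15 had a counterpart within 30 kb in Inv1, 14 in Inv2, 15 in Inv3, 14 in Inv4, 13 in Inv1DelCTCF and 12 in Inv1 ESC. The WT border of the Epha4 domain at 75.61 Mb had a depth of 1.48. It was found at its inverted position in all mutants, at 75.56 Mb in Inv1 (0.96), 75.40 Mb in Inv2 (1.18), 75.21 Mb in Inv3 (1.31) and 75.08 Mb in Inv4 (1.22). Near the shared right breakpoint a boundary was called in each mutant, with depths of 1.02 in Inv1, 0.60 in Inv2, 0.92 in Inv3 and 1.22 in Inv4. In Inv1 it lay at 75.86 Mb, which holds the sequence of a WT boundary at 75.31 Mb (depth 0.53), so a boundary carried there by the inversion and one formed at the breakpoint were not separated in Inv1, Inv1DelCTCF and Inv1 ESC. In Inv2, Inv3 and Inv4 the sequence at the boundary lay 170, 60 and 50 kb from the nearest WT boundary. Outside all inversions the maps had 15 to 18 boundaries each.

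A stripe is a row of raised contact on one side of an anchor. In WT the anchor with the highest score in the shared segment lay at 75.64 Mb, beside the domain border, and its stripe ran toward the rest of the Epha4 domain with a score of 0.65 ± 0.019 (bootstrap SE), a 1.57-fold rise. Toward the gene-dense side the WT score was -0.30 ± 0.042. The flanks of the score lie on both sides of the border, so the border alone can raise the score toward its own domain. An inverted border would turn that side, so a stripe and a border were not told apart in WT or in Inv1 to Inv4. On the inverted chromosomes the score of the same anchor toward the gene-dense side was 0.61 ± 0.022 in Inv1, 0.49 ± 0.034 in Inv2, 0.52 ± 0.043 in Inv3 and 0.64 ± 0.041 in Inv4. On its other side it was 0.16 ± 0.043 in Inv1, 0.34 ± 0.099 in Inv2, 0.43 ± 0.12 in Inv3 and -0.13 ± 0.13 in Inv4. The sides thus differed clearly in Inv1 and Inv4, while in Inv3 they differed by less than 1 bootstrap SE and in Inv2 by under 2, so that which side was the stronger was not resolved within those 2 maps. Against WT, the score rose toward the gene-dense side by 0.80 in Inv2 and 0.82 in Inv3 and fell on the other side by 0.31 and 0.22. The SD of the score difference to WT over 788 bins outside the inversions was 0.051 to 0.109 toward the gene-dense side in these 4 maps. On the other side it was 0.057 to 0.110. Between 310 and 600 kb, beyond the moved part, contact of the anchor was 2.01-fold above its flanks in Inv1, 1.46-fold in Inv2, 1.5-fold in Inv3 and 2.09-fold in Inv4. Between 610 and 1000 kb it was 0.825- to 1.07-fold, and between 1010 and 1500 kb 0.868-fold in Inv1, 0.978-fold in Inv2, 1.001-fold in Inv3 and 1.27-fold in Inv4. Against all bins at the same distance in place of the flanks, the scores were 0.55 in Inv1, 0.14 in Inv2, 0.033 in Inv3 and 0.38 in Inv4, and 1.28 in WT. By that measure the anchor stood little above other bins in Inv2 and Inv3.

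**Figure D3:**
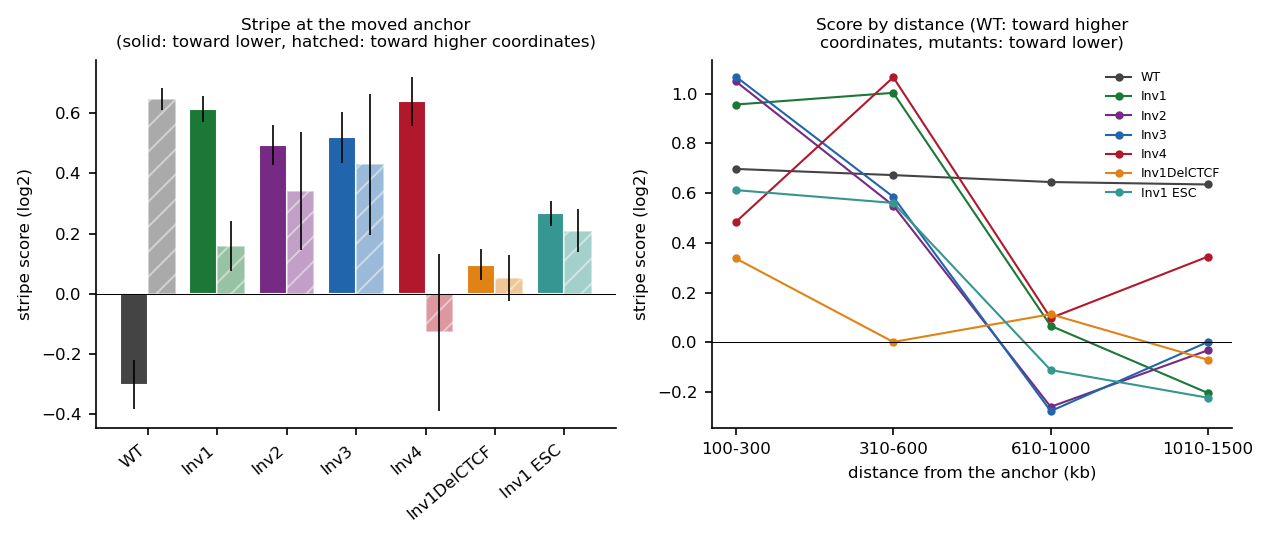
Left, stripe score (y axis, log2) at the moved anchor in each library, solid bars toward lower and hatched bars toward higher coordinates, with 95% bootstrap counting intervals. Right, score (y axis, log2) by distance from the anchor (x axis, kb), 1 line per library. The score was 0.65 toward higher coordinates in WT, and toward lower ones 0.49 to 0.64 in Inv1 to Inv4, 0.097 in Inv1DelCTCF and 0.27 in Inv1 ESC, with scores toward higher coordinates of 0.16 in Inv1, 0.34 in Inv2, 0.43 in Inv3 and -0.13 in Inv4.

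Inv1DelCTCF was compared with Inv1 to see what the deletion changed on the Inv1 chromosome; its extent is not given in the labels. The stripe score toward the gene-dense side was 0.097 ± 0.026 in Inv1DelCTCF and 0.61 ± 0.022 in Inv1, a difference of -0.52. The SD of this difference over the 788 other bins was 0.066. Between 100 and 300 kb the Inv1DelCTCF score was 0.34, against 0.96 in Inv1, and between 310 and 600 kb 0.0012, against 1.004. On the other side of the anchor it was 0.053 ± 0.039. The border beside the anchor had a depth of 0.37 in place of 0.96, and the one near the right breakpoint 1.07 in place of 1.02. Contact of the moved part with the gene-dense stretches was lower but remained far above WT. With the Cnppd1 to Resp18 stretch it was 8.64% in Inv1DelCTCF, 10.3% in Inv1 and 0.544% in WT, and with the Cryba2 to Slc23a3 stretch, which holds Ihh, 5.26%, 7.40% and 0.678%. With the Wnt6 to Fev stretch it was 1.84% against 2.32%. Contact with the sequence between the Inv1 breakpoint and the border, which starts at Dnpep, was 7.74% in Inv1DelCTCF and 5.52% in Inv1. No gene table was used for Inv1DelCTCF.

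Inv1 ESCs were compared with Inv1 limb buds to see which contacts of the Inv1 chromosome differed by tissue. The stripe score toward the gene-dense side was 0.27 ± 0.021 in ESCs and 0.61 ± 0.022 in limb buds, a difference of -0.35, with an SD of 0.118 over the other bins. On the other side of the anchor it was 0.21 ± 0.037 in ESCs. The moved border had a depth of 0.83 in ESCs and the breakpoint border 1.42. Contact of the moved part was 10.6% with the Cnppd1 to Resp18 stretch and 7.65% with the Cryba2 to Slc23a3 stretch, against 10.3% and 7.40% in limb buds. It was lower in ESCs with the Wnt6 to Fev stretch (1.82% against 2.32%) and higher with the Dnpep side of the segment (8.25% against 5.52%). Contact with the remaining Epha4 domain was 5.94% in ESCs and 5.66% in limb buds. A WT ESC map was not analysed here, so tissue was compared on the Inv1 chromosome alone.

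Over the whole maps, bin pairs with 1 bin in the inverted segment changed more than pairs with both bins outside it in all 6 mutants on observed over expected contact, and in 4 of 6 on the deposited balanced values, where the excess was -0.054 in Inv3 and -0.092 in Inv4. The median absolute log2 change to WT was 0.72 against 0.31 in Inv1, 0.82 against 0.58 in Inv2, 0.80 against 0.58 in Inv3, 0.80 against 0.55 in Inv4, 0.69 against 0.32 in Inv1DelCTCF and 0.74 against 0.36 in Inv1 ESC. The WT map was from limb buds, so the values of Inv1 ESC also hold the difference in tissue. In the main setting the excess was smaller in the 3 subtracted maps, where pairs outside the inversions also differed more. Spearman correlation across bin pairs outside the inversions was 0.632 between WT and Inv1, 0.608 between Inv1 and Inv1DelCTCF and 0.541 between Inv1 and Inv1 ESC. It was 0.30 between WT and Inv2 to Inv4, from which WT signal had been subtracted, and 0.432 to 0.452 between Inv1 and these 3 maps, so the low value with WT cannot be read as a change of the chromosome. For pairs touching the Inv4 segment the correlation was 0.272 between WT and Inv1, 0.464 between Inv1 and Inv1DelCTCF and 0.38 between Inv1 and Inv1 ESC. Bin pairs are not independent replicates.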

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

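No paired analysis was possible because each condition was 1 library. Reading the gene contacts from the maps was not run, since the tables do not place the genes. The low contacts of the subtracted Inv2 to Inv4 tables and the depth of single 10 kb bin pairs limit all counts. The cause of the shifts below was not tested. With the smaller pseudocount, genes over 2-fold above and below WT numbered 59 and 12 in Inv1, 35 and 36 in Inv2, and 26 and 15 were below in Inv3 and Inv4; with the larger one they were 17 and 1, 7 and 0, 5 and 0, and 11 and 2 in Inv1 to Inv4. Centring on the median gene gave 21 and 13 in Inv1, 24 and 29 in Inv3, and 24 and 25 in Inv4. It turned the log2 ratios of Ihh (-0.072), Des (-0.15) and Slc4a3 (-0.29) in Inv4, which had exceeded the SD of this ratio over the far genes (0.74). Smaller ratios turned too, such as those of Wnt6, Wnt10a and Mogat1 in Inv4 and of Sgpp2 and Mogat1 in Inv1. Since the median gene may itself be raised by an inversion, a turned ratio does not show a fall. Leaving out genes low in both tables tells nothing here, since with the main pseudocount such genes could not pass 2-fold in Inv1 to Inv3. Touched pairs changed more than untouched ones in all 6 mutants in the main setting and under 7 of the 8 others, but by different amounts: the excess was 0.224 to 0.409 in the main setting, 0.0941 to 0.398 at the same total, 0.598 to 0.739 with the smaller pseudocount and 0.0237 to 0.0732 with the larger one. On deposited KR values they did so in 4 mutants, and the excess was -0.054 in Inv3 and -0.092 in Inv4. Footprint scores with squares of 5 bins were -0.045 in Inv1, 0.18 in Inv2 and 0.016 in Inv4, with squares of 20 bins 0.21 in Inv3 and 0.14 in Inv1DelCTCF, and on deposited KR values 0.27 in Inv4. Boundaries numbered 34 in Inv4 and 33 in Inv1DelCTCF with a 100 kb square and 13 in Inv1 ESC with a 400 kb square, and otherwise stayed within 1.5 times.

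Stripe scores over 100 to 500 kb were 0.74 in WT, 1.03 in Inv1, 0.87 in Inv2, 0.92 in Inv3, 0.87 in Inv4, 0.18 in Inv1DelCTCF and 0.60 in Inv1 ESC. Over 100 to 3000 kb they were 0.49 in WT, 0.40 in Inv1, 0.27 in Inv2, 0.22 in Inv3, 0.42 in Inv4 and 0.19 in Inv1 ESC. An anchor of 1 bin gave 0.71 in WT, 0.76 in Inv1, 0.61 in Inv2, 0.74 in Inv3, 0.78 in Inv4, 0.17 in Inv1DelCTCF and 0.35 in Inv1 ESC, and one of 5 bins 0.57 in WT and 0.56 in both Inv1 and Inv4. Against all bins at the same distance they were 1.28 in WT, 0.55 in Inv1, 0.14 in Inv2, 0.033 in Inv3, 0.38 in Inv4, -0.21 in Inv1DelCTCF and 0.21 in Inv1 ESC. On deposited KR values or the same total they were 0.80 in Inv1, 0.67 in Inv2, 0.75 in Inv3, 0.18 in Inv1DelCTCF and 0.46 in Inv1 ESC. The Inv1DelCTCF minus Inv1 difference stayed negative, at -0.63 on either of these scales, -0.84 over 100 to 500 kb and -0.30 over 100 to 3000 kb. That of Inv1 ESC was -0.54 with 50 kb bins, -0.43 over 100 to 500 kb and -0.21 over 100 to 3000 kb. With the anchor searched within 60 kb, an alternative chosen after seeing the data, the 2 differences were -0.50 and -0.35. The median correlation outside the inversions was 0.173 over all distances and 0.432 in the main setting.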

Other observations

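The tests of subtraction noise, of leftover WT signal, of the stripes outside the inversions and of tissue were chosen after the results had been seen. The anchor search within 60 kb was added after the stripe scores had been seen but before its own value was. The ESC squares below were chosen after the results had been seen, and the minimum of 100 read pairs was set after a first search without it had returned pairs of few reads. Long-range contacts between loci of the Inv1 chromosome that were strong in ESCs and weaker in limb buds were searched in squares of 50 by 50 kb at least 300 kb apart with at least 100 ESC read pairs. The highest excess over Inv1 limb buds lay between 74.80 to 74.85 Mb and 75.75 to 75.80 Mb in file coordinates, at 2.99 times the mean contact of that distance in ESCs (570 read pairs) against 0.539 in Inv1 and 0.687 in Inv1DelCTCF limb buds. The first of these loci also met 78.20 to 78.25 Mb, at 7.60 times the mean (196 read pairs) in ESCs against 2.17 in Inv1 limb buds, 3400 kb away. The second met 78.15 to 78.20 Mb, at 7.55 times (350 read pairs) against 2.87. These 3 pairs headed the list, the latter 2 ending in adjacent squares, and they were selected for their excess, so the sizes lean high. In file coordinates 75.75 to 75.80 Mb lies in the inverted segment. It falls between bins at 75.69 and 75.86 Mb, which hold WT sequence of 75.48 and 75.31 Mb. This locus is thus sequence between the Inv1 breakpoint and the WT border, not of the moved part of the Epha4 domain.

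Epha4 kept more contact with the enhancer region in the Inv2 to Inv4 tables than in the Inv1 table, by 1.11 scaled units on average. The size of this excess depended on the scaling of each table. As log2 ratios to WT, centring on the median gene narrowed the gap to Inv1 in Inv3 and Inv4 and widened it in Inv2. For Inv3, WT signal left over by too small a subtraction was argued against, if tables and maps were subtracted alike: contact across the former right join, as a percent of WT, differed from that of Inv1 by -15.6 points (counting SE 2.67), or, with the longer new distance allowed for, by -3.19 (SE 3.35) as a residual and -12.8 (SE 2.64) as a ratio, where Epha4 would need an excess of 19.6 (SE 8.95). For Inv2 and Inv4 it stays open and could account for the pattern, at 3.27 points on average (SE 2.12) with distance left aside, 5.53 (SE 2.09) by the ratio and 17.8 (SE 2.72) by the residual, against 11.8 for Epha4 (SE 6.30). Noise left by the subtraction also stays open: the Epha4 mean lay above that of Gm17751, Mir6343 and Mir6352, the other genes of its block, by 0.603 of the prediction error of a further gene, their means over the same tables ran from -1.03 to 1.02, and 3 genes are too few to tell. A real residual contact was not tested apart from these.

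The stripe of the moved anchor was weaker in Inv1 ESCs than in Inv1 limb buds. Depth was argued against, since the ESC map was the deeper one. Inv1 limb buds thinned to 50% of their read pairs kept a mean score of 0.61 (0.609 ± 0.017, SD of 10 draws). The thinning adds little, since it lowers anchor and flanks alike. Stripes were also weaker at 8 strong WT stripes outside the inversions, by a mean of -0.18 ± 0.054 (SD), with a largest fall of -0.29. The fall of -0.35 at the moved anchor was larger by 0.17, which is 3.14 SD of those 8 falls but 1.44 times the SD of 0.118 over other bins, so a general weakening could account for part or all of it. The 8 stripes were picked as strongest in WT limb buds, which favours lower scores in ESCs, so their fall alone does not show a general weakening. They are not independent either, since anchors at 72.89 and 72.92, 73.88 and 73.94, and 77.89 and 77.96 Mb flank the same borders. Whether any rest belongs to the tissue or to how the inverted anchor behaves in ESCs cannot be told apart without a WT ESC map.

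The stripe of the moved anchor was weak in Inv1DelCTCF, at 0.097 over the whole range and 0.34 within 100 to 300 kb. Displacement of the anchor in the shortened coordinates was argued against, since the highest score within 60 kb was 0.11. So was depth, since the Inv1DelCTCF map was the deeper one, at 3997486 read pairs against 3903623 in Inv1. The thinned Inv1 score of 0.61 tells little here, since random thinning lowers anchor and flanks alike. A general weakening was argued against by a mean difference to Inv1 of -0.016 ± 0.035 (SD) at the 8 other stripes. A candidate explanation is that the deleted sequence carries most of the stripe, a hypothesis from 1 library per genotype. The border beside the anchor was also weaker, with a depth of 0.37 in place of 0.96. Since the flanks of the score lie on both sides of that border, loss of a stripe and a weaker border were not told apart. The same deletion on the WT chromosome would show whether the WT score of 0.65 depends on the deleted sequence, but would not decide this for the Inv1 chromosome.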
